A study of Mus musculus with 6 samples.

How the data were processed

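RNA from 6 mouse blastocyst samples was measured, each on its own 2-colour oligonucleotide array made by Agilent, with 60-base probes. Per the labels' protocols, 3 batches of 100 dormant blastocysts and 3 batches of 100 activated blastocysts were collected, and poly-A RNA was extracted from each batch. RNA equivalent to 24 blastocysts was amplified linearly over 2 rounds and labelled with Cy3. The common reference, labelled with Cy5, was Universal Mouse Reference RNA, a pool of total RNA from 11 cultured mouse cell lines. No dye swap was made. A dye effect that is the same on every array drops out of the difference between the groups. It does not drop out of a single ratio of embryo to reference. A dye effect that varies with signal intensity need not drop out of either. How dormancy and activation were brought about is not given in the sources used here. Groups and lot numbers were taken from the labels.

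Per the file headers, the authors extracted the scanner images with Agilent Feature Extraction, version A.6.1.1, which is also the tool named in the submitters' processing notes. The deposited scanner files hold spot and local background intensities in scanner units, intensities after background subtraction and dye normalization, quality flags, and a log10 ratio of Cy5 over Cy3. Per the file headers, the 3 dormant arrays were extracted in one run of that software and the 3 activated arrays in another, with the same settings, so extraction run and group cannot be told apart. Each array was a slide of its own. The deposited series matrix holds log10 values whose scale, centring and direction are not stated by the authors. They were found by setting each column against the scanner values of its array. Over 8149 probes with a processed embryo intensity above 1000 on every array, the matrix equalled the embryo over reference log10 ratio plus each probe's mean log10 reference intensity over the 6 arrays, with an SD of the mismatch between 0.0026 and 0.0058. The matrix columns had medians of 2.96, 2.96 and 2.97 for dormant lots 1 to 3, and of 2.97, 2.96 and 2.97 for activated lots 1 to 3, on the log10 scale. The matrix was used as an alternative only.

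The background was corrected with normexp (offset 50) on the mean spot intensity and the median local background, and the ratio was normalized by loess within each array, with control spots and outlier-flagged spots at weight 0, in limma 3.58.1 under R 4.3.3. Values are log2(Cy3/Cy5), that is, embryo over reference. Spots with a non-uniformity or population outlier flag in either channel had weight 0 in the fit, and means leave them out, so n falls below 3 for a few probes. Saturated spots were kept. Each of the 21939 probes had 1 spot per array. A probe was tested where the embryo channel was well above background on at least 3 of the 6 arrays, which left 21557 probes, 3 of them with no estimate because of flagged spots. The test was limma's lmFit and eBayes, activated minus dormant, with Benjamini-Hochberg adjustment over the 21554 remaining probes and a threshold of 0.05.

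The design's gene names are mostly clone identifiers: 21545 of the 21939 probes carry only the identifier of a cDNA clone, which neither the files nor the table of RefSeq names used here pairs with a gene. The other 394 carry a sequence accession. Of these, 117 are RefSeq transcripts, of which 113 matched a mouse gene symbol (assembly GRCm38.p6, unversioned accessions) and 4 did not, and 277 are other accessions that the table does not hold. The text therefore names genes for 113 probes, no gene has more than 1 such probe, and genome coordinates are not printed because the files name no genome build.

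The genes to be named were set by a rule fixed before the data were examined: the 10 largest differences in each direction among probes past the threshold with an official symbol and no overlap between the groups, up to 4 members with the smallest p of each gene list described, and 12 genes whatever their values. No probe met the first part. Of the 12, only Cdx2 was on a named probe, and the other 11 are not analysed here by name. Probes with a clone identifier or an unmatched accession were tested, and some of them may detect these 11 genes. Of 32 gene lists fixed before the data were examined, 17 had no member on a named probe, 14 had at most 4 tested members, and 1, trophectoderm, had the 5 needed for a test. The 113 named genes were therefore also sorted into 12 functional groups, after the names on the array were known and before their values were seen, and up to 2 genes with the smallest p are named from each, of which 1 is not reported here, which left 28 genes in all. Genes named outside these rules are marked as chosen after their values were seen. Lists and groups were tested with limma's camera with a preset correlation of 0.01, with an estimated correlation, and with fry, which asks whether a set's genes move one way on balance. These functions need positive weights, so flagged spots had a weight of 1e-06 there.

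Alternatives were another background correction or offset, Agilent's processed intensities, median centring, Aquantile, the embryo channel alone, the deposited matrix, other filters on dim probes, flagged spots at full weight, an intensity trend with robust estimation, array weights, other thresholds, the lot number as a block, and leaving out each array. A further 3 were chosen after the data were seen: the array's log2 median embryo signal as a covariate, leaving out the 2 arrays that deviated together (dormant 3 and activated 1), and a filter at the 99th percentile of the 314 negative-control spots.

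The fit was tested on simulated values for the 21554 probes, with independent noise and the spread estimated from the arrays. For the comparison of activated with dormant blastocysts, 49% of 100 probes changed by 1 on the log2 scale were recovered and 81% of 100 probes changed by 2, all with the right sign, and 7 unchanged probes were called. With no change simulated, 0 probes were called. A simulated list of 20 genes shifted by 1 had a camera p of 0.00025 with an estimated correlation, and an unshifted list had 0.40. The simulation left out the shared deviations between arrays described with the other observations.

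The number of arrays limits the precision. The median background-subtracted embryo intensity was 141, 215 and 57.4 scanner units on dormant arrays 1 to 3 and 121, 427 and 576 on activated arrays 1 to 3, and that of the reference lay between 77.8 and 120.3. The embryo channel exceeded the 99th percentile of the negative-control spots for 62.5%, 81.1% and 68.4% of probes on the dormant arrays and for 77.3%, 78.6% and 98.4% on the activated arrays. Ratios of dim probes are drawn towards 0 by the offset, so their differences may be understated or overstated. With the offset lowered to 16, the log2 difference of Bmpr1a went from 0.23 to 0.46. That of Bax went from -0.34 to -0.25, and that of Naip2 from -0.20 to -0.19. For 28 pairs of probes with an identical sequence, the log2 difference between the groups differed by 0.029 at the median and by at most 0.14.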

Results

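Gene expression was measured in 3 lots of dormant and 3 lots of activated mouse blastocysts. A blastocyst is the stage of the embryo that implants in the uterus: an outer epithelium, the trophectoderm, encloses the inner cell mass. In dormancy, or delayed implantation, the blastocyst waits in a state of low metabolic and mitotic activity, and activation returns it to a state in which it can implant. Each lot was compared on one array with the same reference RNA from cultured mouse cell lines, and values are log2 ratios of embryo over reference. The labels describe the lots as separately collected batches. The embryo signal was uneven between arrays, with medians from 57.4 scanner units on dormant array 3 to 576 on activated array 3, and activated arrays 2 and 3 were the brightest of the 6.

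**Figure D1:**
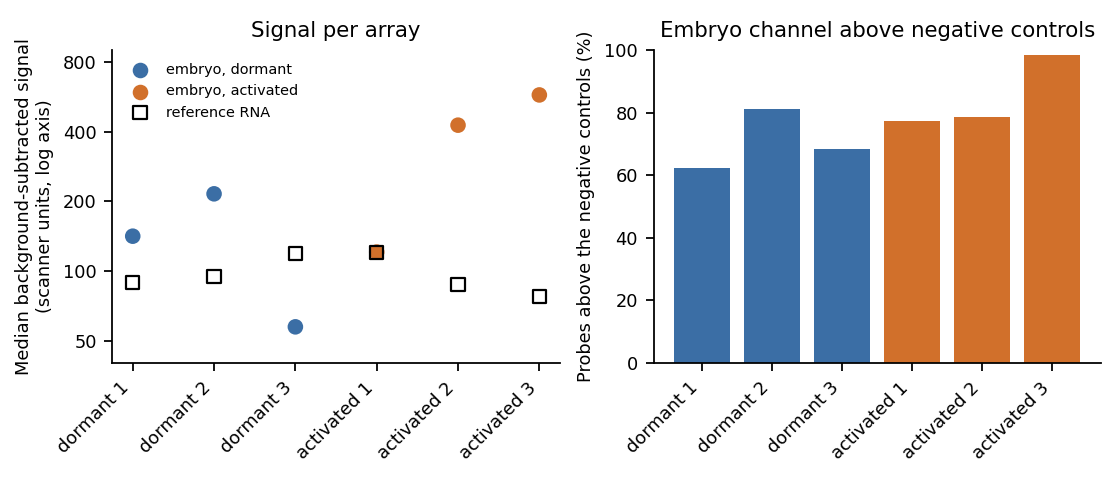
Left, median background-subtracted signal per array in scanner units (log axis), for the embryo RNA (filled circles, blue for dormant and orange for activated) and the reference RNA (open squares). Right, the percentage of the 21939 probes whose embryo signal exceeded the 99th percentile of the negative-control spots, which ran from 62.5% on dormant array 1 to 98.4% on activated array 3.

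The study's title states the question of which genes distinguish blastocyst dormancy from activation. Transcripts detected by 30 probes were higher in activated blastocysts and those detected by 34 were higher in dormant blastocysts, out of 21554 probes tested. The differences ran from 1.61-fold to 6.00-fold with a median log2 size of 1.12, and 44 of the 64 exceeded 2-fold. Of the 64, 57 lay above the negative controls on all 6 arrays. The others were all higher in activated blastocysts and fell short of the controls on dormant arrays only. Clone H3039A06-3 was above them on 0 of 3 dormant arrays and H3068D08-3 on 1. None of the 64 was a probe with a gene symbol: 61 carried a clone identifier and 3 a sequence accession not matched to a symbol, with log2 differences of 1.93, 0.96 and -0.89. The difference of 0.96 left out a flagged spot on dormant array 3, and with that spot it was 0.47 (adjusted p = 0.79). Without background correction, the differences of 1.93, 0.96 and -0.89 became 0.96, 0.28 and -0.42. With an offset of 16, that of -0.89 became -0.97 (limma adjusted p = 0.062).

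The probe for clone C0944B05-3 was higher in dormant blastocysts, at 1.88 ± 0.13 against -0.70 ± 0.20 in activated blastocysts (SD, n = 3 each), a 5.96-fold difference (limma adjusted p = 0.028). Its deposited sequence was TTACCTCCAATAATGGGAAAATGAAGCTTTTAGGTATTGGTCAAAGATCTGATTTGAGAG. The probe for clone H3114D11-3, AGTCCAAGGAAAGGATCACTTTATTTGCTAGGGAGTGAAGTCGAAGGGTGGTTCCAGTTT, stood at 0.067 ± 0.50 in dormant and -2.52 ± 0.093 in activated blastocysts, a 6.00-fold difference. In the other direction, the probe for clone H3131D05-3, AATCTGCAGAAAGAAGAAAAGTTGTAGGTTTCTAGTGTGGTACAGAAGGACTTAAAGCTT, was 4.34-fold higher in activated blastocysts, at 2.28 ± 0.40 against 0.16 ± 0.27. The probe for clone H3080E12-3, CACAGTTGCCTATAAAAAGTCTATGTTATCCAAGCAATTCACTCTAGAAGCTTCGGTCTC, was 3.97-fold higher, at 4.19 ± 0.36 against 2.20 ± 0.17. The adjusted p was 0.042 for H3114D11-3, 0.049 for H3131D05-3 and 0.044 for H3080E12-3. Over all alternatives, the log2 difference ran from -2.86 to -1.43 for C0944B05-3 and from -2.79 to -1.76 for H3114D11-3. It ran from 1.42 to 2.68 for H3131D05-3 and from 1.48 to 2.38 for H3080E12-3. For each clone, the value nearest 0 was that without background correction.

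**Figure D2:**
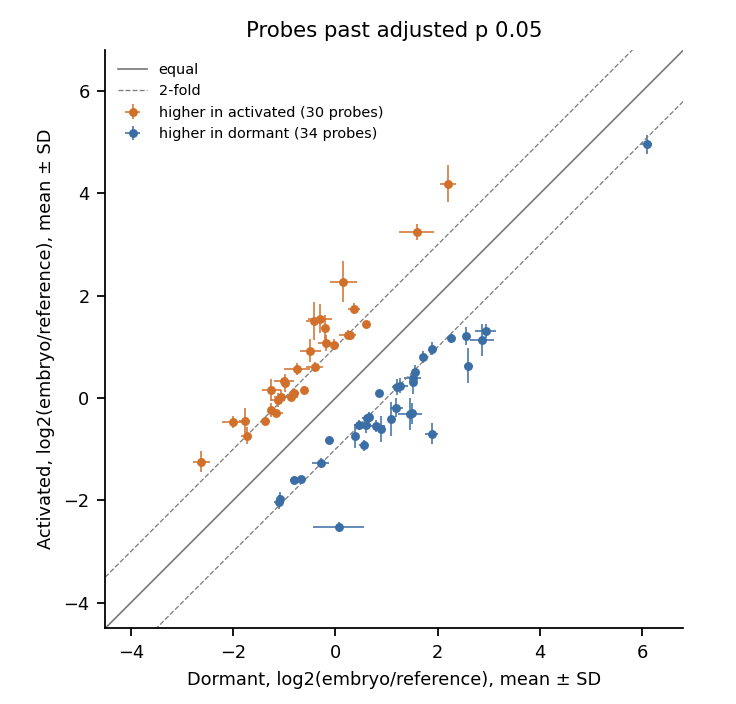
Mean log2(embryo/reference) of the 64 probes past adjusted p 0.05 in dormant (horizontal axis) and activated blastocysts (vertical axis), with SD bars over 3 lots each (2 dormant lots for 1 probe with a flagged spot). Orange marks the 30 probes higher in activated and blue the 34 higher in dormant blastocysts; the solid line is equality and the dashed lines are 2-fold differences, which 44 probes exceeded.

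At an unadjusted p under 0.05 there were 2423 probes, and the other splits of the 6 arrays into 3 and 3 gave 135 to 4859. The counts of 30 and 34 became 0 and 0 without background correction or with median centring, 0 and 1 with Agilent's processed signals, with the deposited matrix or with an intensity trend and robust estimation, 0 and 3 with the embryo channel alone, 411 and 362 with array weights, and 399 and 192 with array brightness as a covariate. They became 0 and 0 without dormant array 1, 2 or 3, without activated array 2 or 3, and without both dormant array 3 and activated array 1, and 0 and 2 without activated array 1. With 1 array left out, the log2 difference ran from -2.69 to -2.50 for C0944B05-3 and from -2.79 to -2.31 for H3114D11-3. It ran from 1.92 to 2.32 for H3131D05-3 and from 1.82 to 2.18 for H3080E12-3. These clones were picked on all 6 arrays.

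Among the genes with a symbol, 109 were tested and 0 passed the threshold in limma, over all probes or adjusted over the named genes alone (smallest adjusted p = 0.68). At an unadjusted p under 0.05 there were 6 of the 109, near the number that this threshold gives with no difference. The log2 difference was positive for each of the 6. Below, each log2 difference is given ± SE, with its lowest and highest value over all alternatives in brackets. Cebpa, a transcription factor of the C/EBP family, stood at 2.28 ± 0.19 in activated and 1.26 ± 0.80 in dormant blastocysts (SD, n = 3 each), a difference of 1.02 ± 0.40 [0.47 to 1.28]. Kpna4, an importin alpha of nuclear import, differed by 0.51 ± 0.19 [0.13 to 1.07], and Gsk3b, a kinase of Wnt signalling, by 0.28 ± 0.099 [0.063 to 0.38]. Tnfrsf11a, the receptor RANK, differed by 0.25 ± 0.076 [0.022 to 0.52], and Fgf3, a fibroblast growth factor, by 0.23 ± 0.092 [0.059 to 0.42]. The adjusted p of these genes ran from 0.28 for Tnfrsf11a to 0.43 for Fgf3. The embryo signal exceeded the negative controls on 3 of 6 arrays for Tnfrsf11a, on 4 for Kpna4 and Fgf3, and on 6 for Cebpa and Gsk3b.

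The trophectoderm list had 5 tested genes, and 0 passed the threshold, over all probes or adjusted over the list alone. Cdx2, the transcription factor that specifies the trophectoderm, stood at 1.36 ± 0.28 in dormant (SD, n = 3) and 1.37 ± 0.72 in activated blastocysts (SD, n = 2, with 1 flagged spot). Its log2 difference of 0.016 ± 0.35 [-0.49 to 0.53] turned to -0.20 with flagged spots kept and to -0.11 with the embryo channel alone. Krt18, a keratin of simple epithelia, differed by -0.081 ± 0.35 [-0.46 to 0.44], and by 0.061 with the embryo channel alone and 0.44 with median centring. Fgfr2, the receptor through which FGF4 sustains trophoblast stem cells, differed by 0.43 ± 0.27 [0.081 to 0.71]. The homeobox gene Esx1 differed by 0.093 ± 0.068 [-0.52 with median centring to 0.77], with a signal above the negative controls on 1 of 6 arrays. The water channel gene Aqp8 differed by -0.24 ± 0.23 [-0.57 to 0.18 with median centring]. The median of the 5 was 0.016 (camera p = 0.49, p = 0.60 with an estimated correlation, fry p = 0.68).

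Growth factors and their receptors included 16 tested genes, of which 0 passed the threshold. Fgf3 and Bmpr1a, a receptor for bone morphogenetic proteins, had the smallest p, and Bmpr1a differed by 0.23 ± 0.097 [0.026 to 0.77] with a signal above the negative controls on 1 of 6 arrays. Of the 6 genes of Notch, Hedgehog and Wnt signalling, 0 passed. The smallest p belonged to Gsk3b and to the receptor gene Notch4, which differed by 0.21 ± 0.10 [0.048 to 0.52], above the controls on 4 of 6 arrays. Of the 13 genes of the TNF family, the interleukins and their receptors, 0 passed. Il6st, which encodes gp130, the signalling receptor shared by LIF and interleukin 6, differed by 0.14 ± 0.084 [-0.30 with median centring to 0.75], above the controls on 1 of 6 arrays.

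Of 12 homeobox genes tested, 0 passed the threshold. Msx2 differed by -0.19 ± 0.090 [-0.56 to -0.037], and Dlx3 by 0.099 ± 0.072 [0.034 to 0.49], above the negative controls on 5 and on 3 of 6 arrays. Of the 10 other transcription factor genes, 0 passed. Cebpb, of the same family as Cebpa, differed by -0.87 ± 0.28 [-1.39 to 0.12] on 1 dormant and 2 activated spots that were not flagged, by -0.17 with flagged spots kept, and by 0.12 with median centring and 0.097 with the embryo channel alone. Only 3 nuclear receptor genes were tested, too few for a group test. Esr2, an estrogen receptor gene, differed by 0.053 ± 0.069 [-0.11 with median centring to 0.45]. Esrrb, an orphan receptor gene, differed by 0.046 ± 0.13 [-0.45 to 0.36], and by -0.45 with median centring and -0.16 with the embryo channel alone. Both were above the controls on 2 of 6 arrays.

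Of the 6 genes for chromatin proteins and modifying enzymes, 0 passed. Cbx3, which encodes heterochromatin protein HP1 gamma, stood at -0.53 ± 0.29 in activated and -1.05 ± 0.35 in dormant blastocysts (SD, n = 3 each), and differed by 0.51 ± 0.22 [0.11 to 1.14]. Kat2b, a histone acetyltransferase gene, differed by -0.27 ± 0.16 [-0.47 to -0.015]. Of 5 cell death regulators, 0 passed. Bax, which promotes apoptosis, differed by -0.34 ± 0.21 [-0.50 to 0.015 with the embryo channel alone]. Naip2, an inhibitor of apoptosis family member, differed by -0.20 ± 0.27 [-0.44 to 0.22], and by 0.068 with Agilent's processed signals and 0.041 with the embryo channel alone, with a signal above the negative controls on 1 of 6 arrays.

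Of 14 genes for adhesion, junctions, cytoskeleton and proteases, 0 passed. Plau, the urokinase plasminogen activator gene, differed by -0.38 ± 0.21 [-0.57 to -0.055] and Ank3, which encodes an ankyrin, by -0.40 ± 0.23 [-0.57 to -0.017]. Of 5 genes for hormones and G protein coupled receptors, 0 passed. Ghrh, the growth hormone releasing hormone gene, differed by -0.16 ± 0.087 [-0.21 to 0.66], and by 0.24 with median centring and 0.66 with the embryo channel alone. The calcitonin receptor-like gene Calcrl differed by -0.075 ± 0.092 [-0.28 to 0.040], above the negative controls on 2 of 6 arrays. Of the 12 genes for nuclear import and other cell maintenance, 0 passed, Kpna4 among them. Of 7 markers of other cell types, 0 passed. The oocyte zona pellucida gene Zp1 differed by 0.18 ± 0.13 [-0.13 with median centring to 0.48], above the controls on 2 of 6 arrays. Cd200 differed by -0.22 ± 0.20 [-0.38 to 0.47], and by 0.0026 without background correction, 0.090 with median centring and 0.47 with the embryo channel alone.

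Leaving out 1 array moved some of these differences by more than 1.5 times. Without dormant array 1, Krt18 stood at -0.12, Naip2 at -0.35, Cdx2 at -0.10 and Esrrb at -0.0073. Without dormant array 2, Fgfr2 stood at 0.71, Aqp8 at -0.0018, Krt18 at 0.29, Cdx2 at -0.019, Esrrb at 0.17, Naip2 at -0.33, Plau at -0.57 and Cd200 at -0.34. Without dormant array 3, Cebpa stood at 0.56, Cbx3 at 0.32, Fgfr2 at 0.19, Aqp8 at -0.43, Krt18 at -0.41, Cdx2 at 0.17, Bax at -0.16, Ank3 at -0.19, Calcrl at -0.041, Zp1 at 0.083, Cd200 at -0.057, Esrrb at -0.022 and Naip2 at 0.068. Without activated array 1, Kat2b stood at -0.44, Aqp8 at -0.16, Krt18 at -0.13, Cdx2 at -0.49, Esrrb at 0.10, Naip2 at -0.37, Calcrl at -0.14, Zp1 at 0.28 and Cd200 at -0.38. Without activated array 2, Krt18 stood at -0.0033, Cdx2 at 0.53, Naip2 at -0.098, Calcrl at -0.046, Zp1 at 0.12 and Cd200 at -0.13. Without activated array 3, Kpna4 stood at 0.33, Bmpr1a at 0.15, Bax at -0.20, Calcrl at -0.035 and Esrrb at -0.018.

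**Figure D3:**
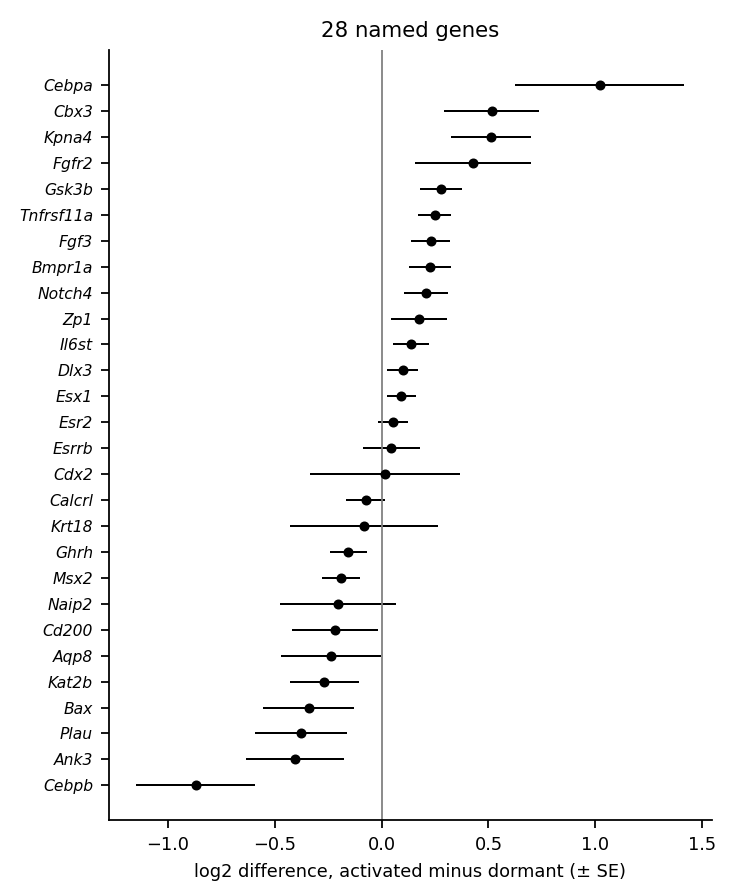
Log2 difference, activated minus dormant, of 28 named genes, with SE bars from the limma fit. 0 of the 28 passed adjusted p 0.05, the values ran from -0.87 for Cebpb (1 dormant and 2 activated spots, -0.17 with flagged spots kept) to 1.02 for Cebpa, and the signs of Cebpb, Cd200, Naip2, Esx1, Aqp8, Krt18, Il6st, Esr2, Esrrb, Ghrh, Zp1, Bax and Cdx2 turned under at least 1 other scaling.

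None of the 11 groups with at least 5 tested genes passed camera's test (adjusted p from 0.90 to 0.92), and none passed with an estimated correlation (adjusted p from 0.91 to 0.92) or with fry (adjusted p from 0.77 to 0.96). The median and camera's direction differed in sign for the TNF family and interleukins (median -0.022), the chromatin proteins (-0.011) and the markers of other cell types (-0.018), each of which camera placed above the other probes, whose median was -0.025. The dormant and activated arrays were extracted in separate runs of the scanner software, so that step and the group cannot be told apart.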

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

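All alternatives were planned before the data were examined except 3: array brightness as a covariate, leaving out dormant array 3 together with activated array 1, and the filter on negative controls. Between 28 and 44 probes in each direction, with all or most of the 64 among them, passed with an offset of 16 (32 higher in activated, 28 higher in dormant, 47 of the 64), after Aquantile, which leaves ratios as they are (30 and 34), with no filter (30 and 34), with the embryo channel above background on all 6 arrays (36 and 42, 63 of the 64) or both channels on at least 3 (34 and 39), with flagged spots kept (33 and 41, 63 of the 64) and with the filter on negative controls (38 and 44). The 30 probes higher in activated and the 34 higher in dormant blastocysts became 0 and 0 without background correction, 0 and 1 with Agilent's processed signals, 0 and 0 with median centring, 0 and 3 with the embryo channel alone, 0 and 1 with the deposited matrix, 0 and 1 with an intensity trend and robust estimation, and 0 and 0 without the 2 dim arrays. They became 411 and 362 with array weights, 399 and 192 with array brightness as a covariate, and 217 and 203 at an adjusted p under 0.10. Leaving out 1 array gave 0 probes higher in activated blastocysts each time and 0 to 2 higher in dormant blastocysts. At an unadjusted p under 0.05 in limma there were 1805 probes without background correction, 1356 with median centring, 4348 without the 2 dim arrays and 1519 to 3446 with 1 array left out. All 64 kept their direction without background correction, with an offset of 16, with Agilent's processed signals, with median centring, with the embryo channel alone, with the deposited matrix and with brightness as a covariate. The 64 were picked from these same arrays and had no overlap between the groups, so the kept direction is no separate support for them. Apart from the looser threshold, the causes of the changes in these counts were not tested, the smaller number of arrays included. The gene lists stayed at 0 past the threshold under each alternative, and none could be tested with the embryo channel above background on all 6 arrays or with the filter on negative controls. The lot number as a replicate block gave 0 and 0 probes, with 1932 at an unadjusted p under 0.05. The labels do not say that lots of the same number were collected together. The deviations of same-numbered dormant and activated arrays correlated at -0.43, 0.48 and -0.67. The deviation that dormant array 3 and activated array 1 share enters these values, so they cannot decide whether lots were paired. The scan date as a block was not run because the sources used here give none, and averaging the probes of a gene was not run because no named gene had more than 1.

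None of the 28 named genes passed the threshold under any alternative, and 36 of their 629 values under alternatives had the opposite sign. With median centring these were Esx1 -0.52, Aqp8 0.18, Krt18 0.44, Il6st -0.30, Cebpb 0.12, Esr2 -0.11, Esrrb -0.45, Ghrh 0.24, Zp1 -0.13 and Cd200 0.090. With the embryo channel alone they were Krt18 0.061, Cebpb 0.097, Esrrb -0.16, Bax 0.015, Naip2 0.041, Ghrh 0.66, Cd200 0.47 and Cdx2 -0.11. With brightness as a covariate they were Esrrb -0.12, Naip2 0.22, Calcrl 0.040, Zp1 -0.029 and Cd200 0.13. Cdx2 turned to -0.20 with flagged spots kept, to -0.11 with array weights and to -0.34 without the 2 dim arrays, Cd200 to 0.0026 without background correction, and Naip2 to 0.068 with Agilent's processed signals. With 1 array left out, Cdx2 ran from -0.49 to 0.53, Krt18 from -0.41 to 0.29, Esrrb from -0.022 to 0.17 and Naip2 from -0.37 to 0.068. Cdx2 stood at -0.10 without dormant 1, -0.019 without dormant 2 and -0.49 without activated 1. Esrrb stood at -0.0073 without dormant 1, -0.022 without dormant 3 and -0.018 without activated 3, Krt18 at 0.29 without dormant 2, and Naip2 at 0.068 without dormant 3. The cause was not tested. Signal over background limits these genes: 47 of the 109 tested exceeded the negative controls on all 6 arrays, and 2 on none.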

Other observations

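The first 6 genes of this paragraph were chosen after their values were seen. Against the reference RNA (log2, mean ± SD over the arrays without a flagged spot), Has2, a hyaluronan synthase gene, stood at 2.14 ± 1.09, Kpna6 at 1.79 ± 0.88 and Cebpa at 1.77 ± 0.76. Has2 was highest on dormant 3 (3.69) and activated 1 (3.04) and lowest on activated 3 (0.94). Kpna6 had the same order, at 2.95, 2.59 and 0.91. Cebpd stood at -4.25 ± 0.94, Cebpb at -3.79 ± 0.56 (n = 3 arrays) and Bax at -2.59 ± 0.33. The embryo signal exceeded the negative controls on 4 of 6 arrays for Cebpd, which ran from -5.15 to -2.43, and on 5 for Bax. Of the trophectoderm list, Cdx2 stood at 1.37 ± 0.41 (n = 5 arrays), Krt18 at 1.04 ± 0.45, Fgfr2 at 0.74 ± 0.42, Aqp8 at 0.24 ± 0.33 and Esx1 at 0.0076 ± 0.056. The 7 markers of other cell types went different ways. Tpbpa, a gene of the later placenta, stood at 0.036 ± 0.038 and above the negative controls on 0 of 6 arrays, Ivl at 0.11 ± 0.042 on 1 of 6, Zp1 at -0.011 ± 0.18 on 2 of 6, and the macrophage gene Lyz2 at -0.19 ± 0.10 on 5 of 6. Lor at 0.51 ± 0.16, Cd200 at 0.67 ± 0.28 and Ptcra at 0.80 ± 0.60 were above them on 6 of 6. The dyes were not swapped, and loess centres each array's ratios on those of its other probes, so these ratios carry any dye bias and compare each gene with the bulk of the array.

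Embryo signal was well above background on all 3 activated and 0 of 3 dormant arrays for 46 probes, and the reverse held for 0 probes. Activated arrays 2 and 3 also had the highest median embryo signals, 427 and 576 scanner units.

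The tests of the group labels and the control by embryo over reference ratios for the clone suffix, below, were chosen after the deviations were seen. Across the 21557 tested probes, dormant array 3 and activated array 1 deviated from their group means in the same direction (r = 0.76 across probes, which are not independent). Their ratios correlated with each other at 0.93, against 0.85 to 0.90 for dormant 3 and 0.85 to 0.86 for activated 1 with the arrays of their own groups, and activated 1 correlated at 0.91 and 0.88 with dormant 1 and 2. Among the 25% of probes with the highest mean intensity of the 2 channels, r was 0.78. Probes dim in the embryo channel but bright in the reference can be among them. The value therefore cannot decide whether the background correction compressed dim embryo signals on these arrays. Probe GC content is argued against by a Spearman rho of -0.0024 with the mean deviation of these 2 arrays. A wrong group label on either array is argued against by the 100 probes with the smallest p between dormant 1 and 2 and activated 2 and 3. Positions ran on a scale from 0 at the mean of the other group to 1 at that of the array's own. Dormant 3 had a median position of 0.94 (95% bootstrap interval over the probes 0.89 to 1.01) and activated 1 of 0.74 (0.67 to 0.79). Probes are not independent, so these intervals do not measure the uncertainty between arrays. A mixed sample was not tested. Shorter amplified products on these arrays stay open: the median deviation of clones with the suffix -5 minus that of clones with -3 was -0.0092 (95% bootstrap interval -0.021 to 0.0055), but the suffixes did not differ in embryo over reference ratio either (-0.0045, interval -0.030 to 0.018), so the suffix may not mark distance from the 3' end. A real difference between the lots was not tested.

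For the 64 probes that passed the threshold, the covariate cannot decide whether a difference in embryo brightness between the groups was the cause. Brightness also varied within groups. The 64 were picked partly for a small spread there, which favoured a small change with the covariate in advance. With each array's median signal as a covariate, 3993 probes were associated with brightness, while the median log2 size of the 64 went from 1.12 to 1.10, a ratio of 0.98, and all 64 remained past the threshold. The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05: the real split gave 64 probes and the highest of the others 0, so 1 of the 10 splits gave as many. Splitting dormant 1, dormant 3 and activated 1 from the other 3 gave 4859 probes at an unadjusted p under 0.05, against 2423 for the real split. Dormant 1, dormant 3 and activated 1 had the lowest median embryo signals. The 4859 therefore cannot be assigned to the samples rather than to array signal. What sets these arrays apart was not tested. The difference between dormant and activated blastocysts that the design names may account for the 64 probes. The separate extraction runs or embryo brightness may as well, and these could not be separated here.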
